A study of Mus musculus with 2 samples.

How the data were processed

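Gene expression was measured in the ventral prostate of male C57BL/6J mice aged 3 months, in a wild-type sample and in a sample labelled homozygous for loss of U19/Eaf2. Each group held 1 sample and each sample 1 array, 2 arrays in all. Per the labels, total RNA was extracted with Trizol and a column kit, and 5 ug was turned into biotin-labelled cRNA for hybridisation to an Affymetrix mouse array with 45101 probe sets. The sample names speak of prostates in the plural, and whether the RNA of several animals was pooled is not given in the sources used here.

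The deposited values were linear probe-set signals, which never went below 0. GCOS 1.4, the Affymetrix GeneChip Operating Software, is named by the submitters' processing notes. Its settings are not given in the sources used here. The mean signal without the highest and lowest 2% of probe sets was 500.0 on both arrays, so that each array had been scaled as a whole. Single genes had not been normalized between arrays. Detection calls were not used here, so low signals could not be told from background probe set by probe set. A floor was used in their place.

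Probe sets were named from the platform annotation. Of 45037 probe sets that were not controls, 34945 were listed with 1 gene symbol, 932 with several and 9160 with none. Through Entrez gene IDs, 34741 of the single-symbol probe sets were matched to a mouse gene table of assembly GRCm38.p6, which was used for names only, and 0 of their symbols differed. Probe sets with several symbols or none entered no gene result. The single-symbol probe sets covered 18193 genes, and each gene was represented by its probe set with the highest mean log2 signal over both arrays, a choice blind to the difference between them. The gene's other probe sets above the floor were examined for the same direction.

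The floor was the 50th percentile of the non-control signals pooled over both arrays, a signal of 166. A gene entered when its higher array reached the floor, and lower values were raised to it. A ratio with an array below the floor is therefore a bound and is written as at least so many fold. Differences were taken as log2 of the signal on the array labelled knockout over that on the wild-type array, with a threshold of 2-fold for counts. No pseudocount was added. With 1 array per group no test was possible, and no p-value, standard deviation between animals or standard error is given. Every comparison describes these 2 arrays. The number of arrays limits the precision. The only spread within the data, that between probe sets of the same gene, covers probe-level error and leaves out animals, dissection and hybridisation.

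There were 37 gene lists, covering partners and chromosomal neighbours of Eaf2, prostate secretion and androgen response, cell types of the gland and of tissue that could be taken with it, signalling, stress, metabolism and immunity. For each list the median log2 ratio of its measured members was set against 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list was said to stand apart when its percentile was below 2.5 or above 97.5. Lists with under 5 measured members were given values only. Some genes belong to 2 lists. The named genes were Eaf2, the 12 genes with the highest and the 12 with the lowest log2 ratio among those measured on both arrays, and the 6 with the largest bound in each direction. In each list, up to 2 members with the highest and 2 with the lowest log2 ratio were named, together with any Eaf2 partner or neighbour that differed 2-fold. Clone and predicted gene names were counted and not named. A gene whose other probe sets went the other way stayed named, with that fact beside it.

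The grouping, floor, thresholds, gene lists, naming rule and the first set of alternatives were fixed before the data were examined. That set held median centring, quantile normalization, a loess of log2 ratio on mean log2 signal with a span of 0.4, floors at the 30th and 70th percentiles, no floor, a pseudocount of 50, 3 other ways to choose a gene's probe set, fold thresholds of 1.5 and 3, the mean in place of the median over list members, and random lists also matched on the number of probe sets. The choices of probe set included leaving out those with names ending in _s_at, _x_at or _a_at, called suffixed probe sets here. These hold cross-hybridising types but are not limited to them. Alternatives chosen after seeing the data kept genes with no opposite probe set, kept genes with at least 2 probe sets that all went the same way, or left Car3 out of the adipocyte list.

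The calculations were tested on 5 simulated pairs of arrays with noise of 0.25 (SD, log2) per array, with 200 genes altered 2-fold or 4-fold among 11424 to 11452 entering genes. Of genes altered 2-fold, 42.5% passed the 2-fold threshold, and of genes altered 4-fold, 92.1% did, against 0.363% of unaltered genes. Of simulated lists of 20 genes, 3 of 50 stood apart with no shift, 34 of 50 with a shift of -0.3 and 50 of 50 with a shift of -0.6. A shift of -0.3 over a list of that size was therefore often missed in the simulation. Its noise was the same at all signals and independent between probe sets, and all members of a list shifted alike. These shares therefore need not hold for the measured arrays. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.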

Results

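U19/Eaf2, ELL-associated factor 2, is an androgen-induced protein that binds ELL-family transcription elongation factors and is studied as a tumour suppressor of the prostate. The series profiled mRNA in the ventral prostate, the androgen-dependent secretory lobe of the mouse gland, to ask which transcripts differ when U19/Eaf2 is lost. It held 1 wild-type and 1 knockout sample, each hybridised to 1 array, and so had no replicates. Both arrays read 45101 probe sets. The median signal was 177 on the wild-type array and 154 on the array labelled knockout, with maxima of 63443 and 65368. The floor of 166 was reached by 51.6% of non-control probe sets on the wild-type array and by 48.4% on the other. Over the 24267 probe sets that entered, with values below the floor raised to it, log2 signals correlated with a Pearson r of 0.970. Over all non-control probe sets, with no value raised, r was 0.928. Probe sets are not independent replicates.

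The Eaf2 transcript itself read equally on both arrays. Its only probe set with a single gene symbol gave a signal of 691 on the wild-type array and 702 on the array labelled knockout, a log2 ratio of 0.02. These signals were higher than those of 78.7% and 79.4% of non-control probe sets. The part of the transcript that the deletion removed is not given in the sources used here, and a probe set outside that part checks nothing about the labels. The sample is therefore called the array labelled knockout, and every direction below rests on that label.

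The 3' over 5' ratios, a guide to RNA degradation, were higher on the array labelled knockout for Actb and for Gapdh. The control probe sets for the 3' end of Actb, which encodes cytoplasmic beta-actin, read 1.25 times those for its 5' end on the wild-type array and 1.65 times on the array labelled knockout, a log2 change of 0.41. For Gapdh, a glycolytic enzyme, these 3' over 5' ratios were 0.714 and 0.847, a log2 change of 0.25. Both changes were smaller than 0.499, the SD of the difference in log2 ratio between 2 probe sets of the same gene. They do not decide whether the RNA of the 2 samples differed in degradation. The Actb signal was lower on the array labelled knockout at all 3 positions, with log2 ratios of -0.23 at the 3' end, -0.52 in the middle and -0.64 at the 5' end. The 9 bacterial hybridisation controls had log2 ratios from -0.17 to 0.34, with a median of 0.04.

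Among genes measured on both arrays, the highest ratio on the array labelled knockout was that of Car3, a carbonic anhydrase abundant in fat and muscle. Car3 read 234 on the wild-type array and 1278 on the other, 5.47-fold higher, and its other probe set in use read 149, below the floor, and 378. Uba6, an activating enzyme for ubiquitin, read 421 and 1505, 3.57-fold higher, with log2 ratios from 0.19, a bound, to 1.07 in its other 3 probe sets above the floor. Ptpn2, a tyrosine phosphatase, was 2.84-fold higher, with a log2 ratio of 0.67 in its other probe set, and Ptchd1, a patched-domain membrane protein, 2.80-fold higher, with 0.24 to 0.42 in its other 3. The lowest ratio among genes measured on both arrays was that of Sema3f, a secreted semaphorin, at 1563 and 205, 7.64-fold lower in its only probe set above the floor. That probe set is of the suffixed kind. Of the other Sema3f probe sets, all below the floor on both arrays, that at 40.0 and 55.1 went the opposite way. That at 85.3 and 17.1 went the same way.

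Of 11671 genes that entered, 69 were at least 2-fold higher and 103 at least 2-fold lower on the array labelled knockout, 1.47% together. Of these, 58 higher and 71 lower genes were measured on both arrays, and 4 and 5 carried clone or predicted names. The split between directions moved with the scaling, to 82 higher and 73 lower under quantile normalization and to 86 and 76 under loess. The counts moved more with the floor, to 203 and 505 with it at the 30th percentile and to 37 and 25 at the 70th. Among the higher genes with at least 2 probe sets above the floor, all probe sets went the same way in 10 of 32, and among the lower genes in 15 of 32.

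The other genes highest on the array labelled knockout were Gpaa1, a subunit of the transamidase that attaches GPI anchors (3.79-fold), Spr, sepiapterin reductase (2.94-fold), Acvr1c, an activin-type receptor (2.93-fold), Gkap1, a G-kinase anchoring protein (2.90-fold), Scgb2b27, a secretoglobin (2.83-fold), Ank3, the membrane adaptor ankyrin-G (2.80-fold), Braf, a kinase of the ERK cascade (2.80-fold), and Copg2, a subunit of the COPI coat (2.71-fold). Other probe sets went the opposite way for Gpaa1 (2 of 3), Acvr1c (1 of 2), Ank3 (2 of 5) and Braf (5 of 8). Among genes below the floor on the wild-type array, Lce1h, a gene of the late cornified envelope family, was at least 6.58-fold higher and Spats2 at least 4.25-fold higher. The Lce1h probe set, the only listed for that gene, is of the suffixed kind. Shroom4, Myo7b, Camta1 and Map3k9 followed at no less than 2.84-, 2.63-, 2.24- and 2.23-fold higher.

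Among the genes lowest on the array labelled knockout, Slc35a5, of the nucleotide-sugar transporter family, read 4011 and 1451, 2.76-fold lower, and its other 4 probe sets had log2 ratios from -1.39, a bound, to -0.18. Nudt7, a peroxisomal hydrolase of coenzyme A, was 2.64-fold lower, with a log2 ratio of -0.24 in its other probe set above the floor. Col4a2, a chain of basement-membrane collagen, was 2.64-fold lower, the magnesium-transporter relative Slc41a3 2.77-fold lower, the synaptic adhesion gene Nrxn3 2.62-fold lower, Baalc 2.62-fold lower and the RNA-binding Lsm7 2.46-fold lower, each in a single probe set above the floor. Ints14, a subunit of the Integrator complex (3.13-fold lower), Dscam, an adhesion molecule (2.90-fold), Snhg11, a host of small nucleolar RNAs (2.84-fold), and Nup62, a nucleoporin (2.63-fold), each had 1 probe set that went the opposite way. Below the floor on the array labelled knockout, Def8 was at least 4.53-fold lower and B4galt4, a galactosyltransferase, at least 4.05-fold lower. The urate transporter Slc22a12 was at least 3.56-fold lower in 1 of its 2 probe sets and higher in the other, and Fcgbp, Dyrk1b and Adamtsl4 were at least 3.04-, 3.02- and 2.89-fold lower.

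Different probe sets of the same gene shared their direction only slightly more often than not. Among 4497 genes with at least 2 probe sets above the floor on both arrays, a pair drawn at random from each gene had the same sign in 2448, or 54.4% (95% Wilson interval 52.98 to 55.89%, across genes, which are not replicates). The SD of the difference within a pair was 0.499 on the log2 scale, or 0.353 per probe set, close to the SD of 0.373 of the log2 ratio over all genes. Where the probe set drawn earlier differed by at least 2-fold, the other had the same sign in 41 of 65 pairs.

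**Figure D1:**
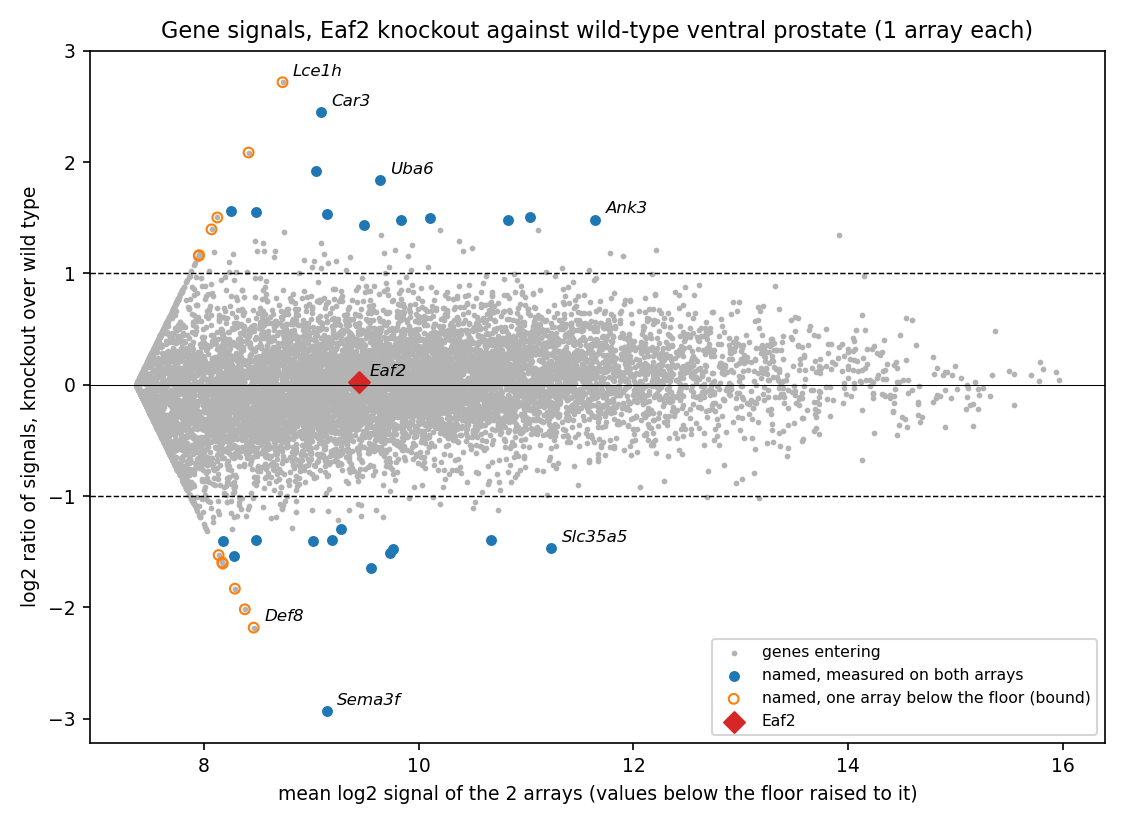
Each point is a gene, with its mean log2 signal over the 2 arrays on the x axis and its log2 ratio, array labelled knockout over wild type, on the y axis; dashed lines mark the 2-fold threshold and open circles are bounds. Eaf2 lies at 0.02, while Car3 lies at 2.45 and Sema3f at -2.93.

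The gene lists asked which cell types and pathways of the gland differed as groups. Of 37 lists, 30 had at least 5 measured members, and 9 of those stood apart from random lists of matched signal, 6 with lower and 3 with higher medians on the array labelled knockout. At this threshold 1.5 lists of 30 would stand apart by chance if members of a list varied like randomly drawn genes. Genes of the same cell type or pathway can vary together between samples, so the 9 lists cannot be read as an excess over chance. With 1 array per group, each difference below came with the Actb 3' over 5' ratio of 1.65 against 1.25.

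Markers of the prostatic stroma were lower as groups. Smooth muscle markers, the contractile genes of the sheath around prostatic ducts, had a median log2 ratio of -0.30 and lay at the 0.05th percentile of random lists, with 13 of 15 members lower. Calponin Cnn1 read 2326 and 1271, a log2 ratio of -0.87, and the myosin light chain Myl9 had -0.86, whereas Lmod1 had 0.04 and the tropomyosin Tpm1 0.13. Fibroblast and matrix genes had a median of -0.20 at the 0.67th percentile, with 17 of 19 members lower. The matrix protein Fbln2 was 2.17-fold lower and the growth factor receptor Pdgfra 1.72-fold lower, while Col6a2 had a log2 ratio of 0.22 and Fbln1 of 0.09. Tpm1, Fbln1 and Col6a2 had probe sets that went the opposite way. The Actb 3' over 5' ratio of 1.65 against 1.25 lay on the same array as these lower signals. With suffixed probe sets left out, the smooth muscle list lay at the 2.705th percentile and no longer stood apart.

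Angiogenesis regulators, genes that steer vessel growth, were also lower, with a median of -0.30 at the 0.55th percentile and 12 of 18 members lower, on the array where the smooth muscle and matrix lists were lower too and the Actb 3' over 5' ratio was 1.65. The lowest members were Angptl4, at least 1.69-fold lower, and Serpinf1, an inhibitor of vessel growth that the matrix list also holds, at -0.72. The hypoxia-inducible factor Hif1a had a log2 ratio of 0.34, with a probe set that went the opposite way, and the vascular co-receptor Nrp1 of 0.25. Endothelial markers did not stand apart, with a median of -0.12 at the 38.7th percentile, which became 0.01 under quantile normalization. Their lowest members were Emcn at -0.72 and Esam at -0.68, and their highest were Cldn5 at 0.13 and Eng at 0.06. The angiogenesis list lay at the 5.52nd percentile with the floor at the 70th percentile and at the 11.4th percentile with the probe set closest to no change.

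Immediate-early genes, transcribed within minutes of a stimulus, were lower with a median of -0.25 at the 0.53rd percentile, 16 of 21 members lying below 0. The phosphatase gene Dusp1 read 724 and 447, a log2 ratio of -0.70, and Junb -0.65. The transcription factors Klf6 at 0.39, with 2 of 5 probe sets opposite, and Fosl2 at 0.38 were the highest. Interferon-stimulated genes, the antiviral effector group, had a median of -0.32 at the 0.62nd percentile, with 17 of 19 members lower. The guanylate-binding protein Gbp2 was at least 1.88-fold lower and the interferon regulatory factor Irf7 was 1.69-fold lower. Ifit2 had a log2 ratio of 0.45 and Oas1a of 0.09. These lower signals lay on the array with the higher Actb 3' over 5' ratio, 1.65 against 1.25, and with the lower smooth muscle and matrix lists, where macrophage markers had a median of -0.26.

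Ribosomal protein genes had a median of -0.10, at the 1.38th percentile, since random lists of such bright genes had a median of 0.09. Of 17 members 12 were lower, led by Rps9 at -0.45 and Rps19 at -0.26, while Rps6 had 0.38 and Rpl13a 0.12. Rps9 and Rpl13a had probe sets that went the opposite way. The list no longer stood apart in 6 of 12 alternatives, including quantile normalization (6.88th percentile) and loess (2.525th percentile).

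Adipocyte markers were higher as a group on the array labelled knockout, with a median of 0.53, 1.44-fold, at the 99.9th percentile, and 5 of 7 measured members higher. Car3 led at 2.45, followed by Fabp4, the fatty-acid carrier of adipocytes, which read 559 and 1001, 1.79-fold higher, while its other probe set above the floor read 502 and 512. The adipokine Retn had a log2 ratio of -0.18 and the lipid-droplet protein Plin4 of -0.31. These higher signals lay on the same array as the Actb 3' over 5' ratio of 1.65. The list lay at the 92.4th percentile with the probe set closest to no change, and the floor at the 70th percentile left too few members.

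Cholesterol synthesis genes were higher with a median of 0.23 at the 98.5th percentile, 10 of 14 members lying above 0, on the array where adipocyte markers were higher too. Fdps, which makes farnesyl diphosphate, was 1.72-fold higher and the sterol demethylase Cyp51 1.54-fold higher. Squalene synthase Fdft1 had a log2 ratio of -0.21, with a probe set that went the opposite way, and Nsdhl of -0.09. This list lay at the 95.8th percentile with the floor at the 30th percentile and at the 95.3rd percentile with no floor. Fatty acid synthesis genes had a median of 0.18 at the 96.3rd percentile and did not stand apart, though they did in 5 of 12 alternatives, all as higher. Fasn, the fatty acid synthase, had a log2 ratio of 0.49 and Acss2 of 0.34, against -0.44 for Elovl7 and -0.31 for Me1, the last 2 with an opposite probe set each.

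Cell cycle genes had a median of 0.17 at the 98.7th percentile, with 9 of 14 measured members higher. The ribonucleotide reductase subunit Rrm2 had a log2 ratio of 0.63, with 2 of 3 probe sets opposite, and the replication helicase subunit Mcm2 of 0.54. The mitotic genes Cdc20 and Cdk1 had -0.27 and -0.19. The median turned to -0.002125 with the median over probe sets, to -0.05 without suffixed probe sets and to -0.004437 with the probe set closest to no change, so that its direction depended on the choice of probe set.

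**Figure D2:**
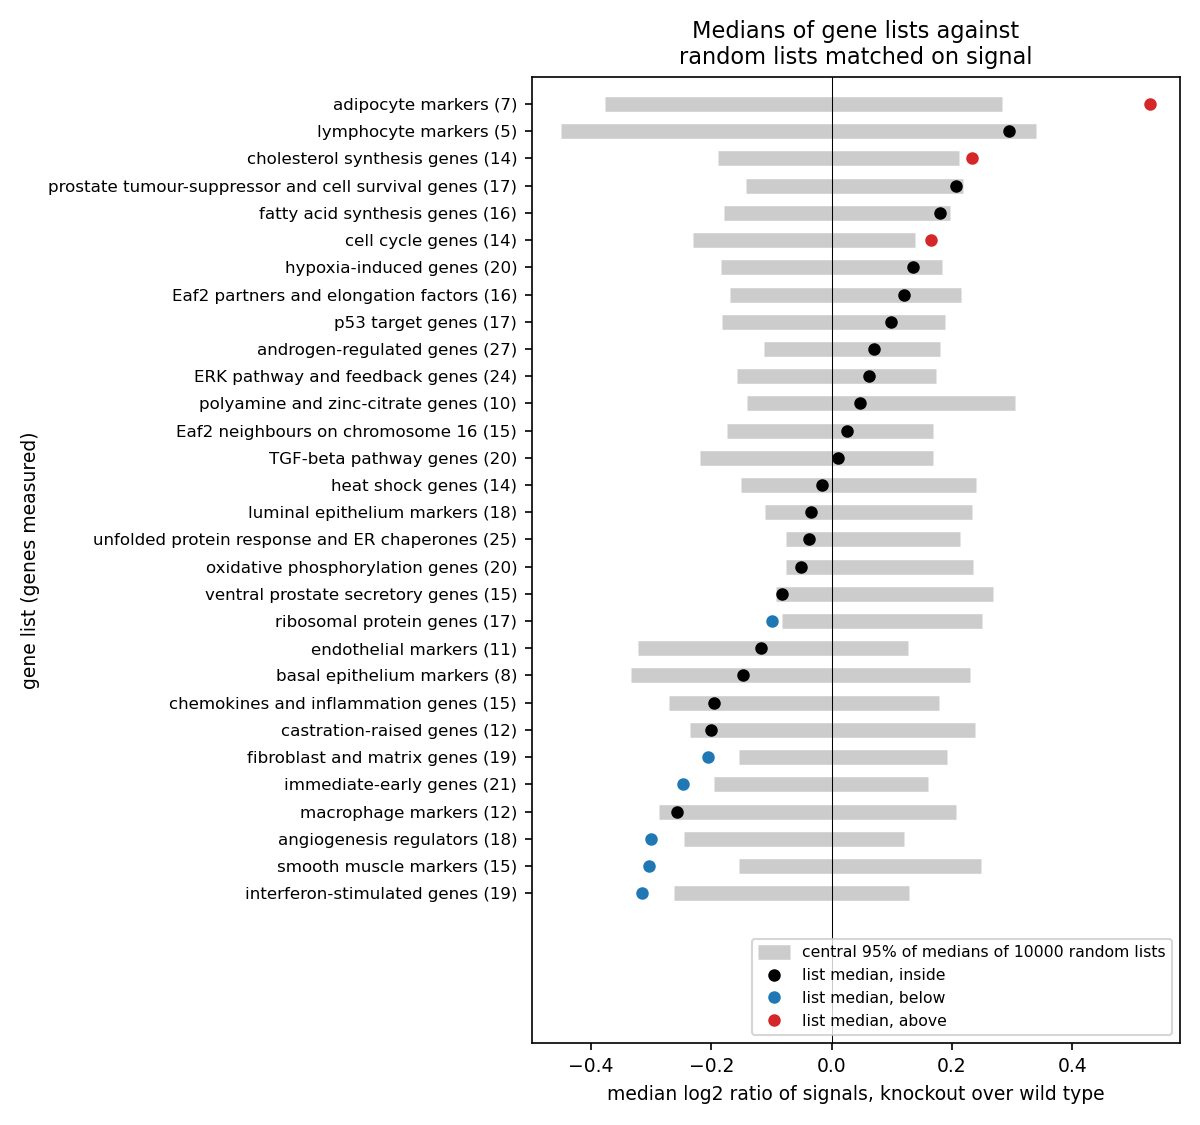
The x axis gives each list's median log2 ratio, array labelled knockout over wild type, as a point, with the number of measured genes in brackets on the y axis; grey bars span the central 95% of medians of 10000 random lists. Points below the bar in 6 lists include smooth muscle markers at -0.30, and points above it in 3 lists include adipocyte markers at 0.53.

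Genes tied to Eaf2 did not stand apart. Its partners and other elongation factors had a median of 0.12 at the 82.9th percentile, 10 of 16 members lying above 0 and 0 differing by 2-fold. The super elongation complex scaffold Aff1 read 2212 and 3621, 1.64-fold higher with the same direction in 3 of 3 probe sets, and the cyclin Ccnt2 had a log2 ratio of 0.50 with 2 of 5 probe sets opposite. Nelfa, of the negative elongation factor, had -0.45 and Ell itself -0.42. The neighbours of Eaf2 on chromosome 16 had a median of 0.03 at the 64.6th percentile, 0 of 15 differing by 2-fold. Slc15a2 had a log2 ratio of 0.25 and Ccdc58 of -0.32, each with opposite probe sets, Casr a bound of 0.22 and Ildr1 -0.31.

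Secretory and androgen-dependent genes of the gland did not stand apart as groups. Ventral prostate secretory genes had a median of -0.08 at the 3.46th percentile, with 8 of 15 lower. The protease inhibitor Spink5 read 20123 and 30220, 1.502-fold higher, and the protease Tmprss2 had a log2 ratio of 0.53 with an opposite probe set. The transcription factor Spdef had -0.56 and Fxyd3 -0.42. This list stood apart without suffixed probe sets, at the 0.08th percentile. Androgen-regulated genes had a median of 0.07 at the 68.0th percentile, with Camkk2 at 0.58 and Pmepa1 at -0.57, a bound, and Ndrg1 at -0.45, Camkk2 and Ndrg1 having an opposite probe set each. Genes that castration raises had a median of -0.20 at the 4.84th percentile, with 8 of 12 lower, from the matrix protein Mgp at -0.76 and Gsta4 at -0.46 to Tgfbr2 at 0.26, with an opposite probe set, and clusterin, Clu, at 0.33 with the same direction in 4 of 4 probe sets. This list stood apart with the floor at the 70th percentile, at the 2.13rd percentile of random lists, while its median was -0.005355 with the floor at the 30th percentile and with no floor.

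Epithelial markers, for the secretory luminal cells and the basal cells beneath them, lay inside the range of random lists. Luminal markers had a median of -0.03 at the 16.1st percentile, which was 0.015 under median centring. The claudin Cldn4 was 2.08-fold higher and E-cadherin, Cdh1, 1.29-fold higher, while Cldn3 was 1.38-fold lower with the same direction in 4 of 4 probe sets and the keratin Krt19 1.31-fold lower. Basal markers had a median of -0.15 at the 28.1st percentile, from Jag2 at -0.73, with an opposite probe set, and Krt5 at -0.62 to Trp63 at 0.09 and Dst at 0.72.

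Leukocyte lists also stayed inside that range. Macrophage markers had a median of -0.26 at the 4.02nd percentile, with 8 of 12 lower. Cd68 and Fcgr3 had bounds of -0.58 and -0.52, against 0.25 for the protease Ctss and 0.22 for Cd14. This list stood apart without suffixed probe sets, at the 0.71st percentile, and with the probe set closest to no change, at the 1.24th. Lymphocyte markers had a median of 0.29 over 5 genes at the 96.2nd percentile. The immunoglobulin chain Ighm had 0.53, with 3 of 4 probe sets opposite, Ptprc 0.33, Jchain 0.25 and the B-cell antigen Ms4a1 -0.04, which turned positive under median centring, quantile normalization and loess. The list median was -0.092 with no floor and -0.014 with the median over probe sets, and with the probe set closest to no change the list stood apart at the 97.8th percentile. Chemokines and inflammation genes had a median of -0.19 at the 9.60th percentile, yet the neutrophil-associated lipocalin Lcn2 was 2.16-fold higher and the acute-phase gene Saa3 1.92-fold higher, against 1.85-fold lower for the cytokine Il18 and 1.43-fold lower for Ccl8.

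**Figure D3:**
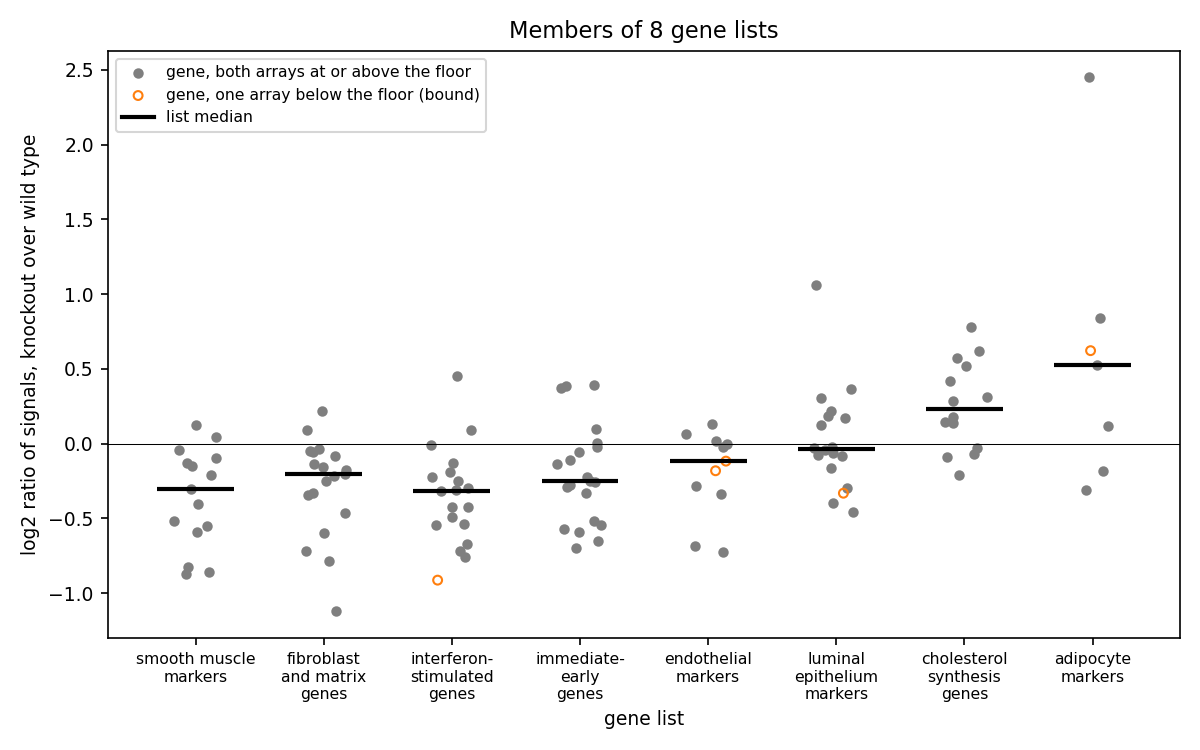
Each point is a gene of 8 lists, named on the x axis, with its log2 ratio, array labelled knockout over wild type, on the y axis; black lines are list medians and open circles are bounds. Of smooth muscle members 13 of 15 lie below 0, while 5 of 7 adipocyte members lie above it, led by Car3 at 2.45.

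Survival genes held the brightest 2-fold difference among the lists. Mcl1, which keeps cells from apoptosis, read 9655 and 24560, 2.54-fold higher. The direction was the same in 6 of 6 probe sets, but not all of them were at least 1.5-fold higher. The transcription factor Foxo1 was 1.54-fold higher with 1 of 3 probe sets opposite. The mTOR inhibitor Tsc2 was 1.504-fold lower and the kinase Akt1 1.31-fold lower with the same direction in 3 of 3 probe sets. The list of prostate tumour-suppressor and survival genes had a median of 0.21 at the 96.8th percentile and did not stand apart. It did in 6 of 12 alternatives, among them quantile normalization at the 98.5th percentile and loess at the 98.2nd.

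Signalling lists were divided in direction. In the ERK pathway, with a median of 0.06 at the 72.5th percentile, Braf had a log2 ratio of 1.48 and the adaptor Grb2 of 0.78, each with opposite probe sets, whereas the feedback phosphatases Dusp5 and Dusp6 had a bound of -0.38 and a value of -0.33. The mean over its members, in place of the median, was 0.19 at the 99.3rd percentile. Targets of p53 had a median of 0.10 at the 85.2nd percentile, with Zmat3 at 0.89 and Trp53inp1 at 0.72, the latter with an opposite probe set, against the cell cycle inhibitor Cdkn1a at -0.56. Thbs1, an inhibitor of vessel growth, read 523 and 376, 1.39-fold lower, and its other probe set 572 and 336. TGF-beta pathway genes had a median of 0.01 at the 64.5th percentile, from Smad4 at 0.65 and Id2 at 0.44 to Ltbp1 at -0.58 and Tgfbi at -0.82, 2 of 3 Tgfbi probe sets being opposite.

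The stress lists, and those of polyamines, zinc and citrate and of oxidative phosphorylation, did not stand apart. Hypoxia-induced genes had a median of 0.13 at the 91.2nd percentile, with Car9 at no less than 0.55 and the hexokinase Hk2 at 0.51, against Ddit4 at -0.84 and P4ha2 at -0.47. Heat shock genes had a median of -0.02 at the 28.8th percentile, with the chaperones Hspb1 and Hspa1b both at -0.54, Hsph1 at 0.40, with an opposite probe set, and Chordc1 at 0.21. Unfolded protein response genes and chaperones of the endoplasmic reticulum had a median of -0.04 at the 7.41st percentile. In that list the disulfide isomerase Pdia4 was 2.63-fold higher and the stress sensor Ern1 1.66-fold higher, both with opposite probe sets, while Sdf2l1 was 1.60-fold lower and Hyou1 1.49-fold lower. Under median centring the medians of these last 2 lists were 0.03 and 0.01, and with the median over probe sets the chaperone list lay at the 2.145th percentile. Polyamine and zinc-citrate genes had a median of 0.05 at the 40.8th percentile, between Srm and Mt1, both at -0.29, Slc30a4 at 0.24 and Sat1 at 0.34, with an opposite probe set for Mt1. Oxidative phosphorylation genes had a median of -0.05 at the 5.47th percentile, between Ndufa4 at -0.37, Cox6c at -0.30, Cox5a at 0.33 and Uqcrc2 at 0.55, with an opposite probe set each for Cox6c and Cox5a.

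Lists of tissues next to the gland had too few measured members for a percentile. Secretory genes of the seminal vesicle and other lobes had a median of -0.18 over 4 genes, with Tgm4 at least 1.65-fold lower. Markers of urothelium had -0.54 over 4 genes, of skeletal muscle 0.08 over 4, of peripheral nerve -0.14 over 3 and of neutrophils and mast cells -0.05 over 3. Among the urothelium markers, Upk1a read 4829 and 3413, and Upk1b 1132 and 755 with the same direction in 4 of 4 probe sets. Upk3a had a bound of -0.61 and Upk2 a log2 ratio of 0.17. The only measured red blood cell gene, Alas2, had -0.39. Of the neuroendocrine markers 0 reached the floor.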

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

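The tests of background, labels, probe-set position, stroma share, RNA degradation, Car3 and fat were chosen after the results had been seen. The 3 scalings were fixed before the data were examined, and setting them against these patterns was chosen afterwards. Probe sets that entered no gene result also held 2-fold differences. Of 9160 probe sets not listed with a gene, 3171 entered, and 18 were at least 2-fold higher and 61 at least 2-fold lower on the array labelled knockout, 2.49% together. Of 932 probe sets listed with several genes, 558 entered, and 2 were higher and 6 lower, 1.43% together.

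The Eaf2 probe set read 691 and 702. Background at the level of the Bacillus and trp controls is argued against by its signal on the array labelled knockout, 11.03 times the highest of them. That highest control signal, 63.7, was below the 30th percentile of non-control signals, 65.8, so most probe sets exceeded it. Higher background is therefore not excluded, and the ratio of 11.03 does not show which transcript was bound. A mislabelled sample stays open, because the log2 ratio of 0.023 would also arise if the probe set read a part of the transcript that the knockout keeps. That explanation stays open too, since Eaf2 had only 1 probe set with a single gene symbol and no further one could be examined. The position of the probe set within the transcript was not used here.

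Smooth muscle markers and matrix genes were lower together, in 30 of 34 members. Scaling or an intensity-dependent bias was not tested by the percentiles, because random lists matched on signal move with such a shift too. Under median centring, quantile normalization and loess neither list went above the 0.67th percentile, which therefore decides little. The medians stayed negative under these scalings, for smooth muscle at -0.25, -0.28 and -0.33 and for matrix genes at -0.16, -0.24 and -0.24. A smaller share of stroma in the tissue taken stays open: the SD of the members' log2 ratios, 0.327, lay at the 31.5th percentile of 2000 matched random lists (central 95% from 0.253 to 0.476), neither narrower nor wider than chance lists, which decides nothing. More degraded RNA on the array labelled knockout cannot be excluded, as the Actb 3' over 5' ratio was higher there by 0.41 (log2) and probe positions were not used here. Loss of Eaf2 itself, the difference the design names, stays open and untested with 1 array per group.

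Adipocyte markers were higher in 5 of 7 members. Car3 alone is argued against for the main choice of probe set only, with the list at the 98.2nd percentile without it. With the probe set closest to no change even the full list lay at the 92.4th percentile. Scaling was not tested by the percentiles, the lowest being 99.89 under the 3 scalings, because the matched random lists move with it. The list median was 0.58, 0.57 and 0.56 under median centring, quantile normalization and loess. Fat taken with the tissue could account for the higher adipocyte list and stays open: the lowest member, Plin4 at -0.31, lay within 0.705, 2 times the SD of a single probe set. Of abundant adipocyte transcripts, named here after their values were seen, Adipoq read 13.8 and 255, Lpl 569 and 821, and Scd1, which the fatty acid list also holds, 9008 and 9758 with an opposite probe set, while Cidec at 24.7 and 30.9 and Lep at 13.4 and 11.5 stayed below the floor and a second Fabp4 probe set read 502 and 512. An effect of Eaf2 loss stays open and untested.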

How the results depend on the processing

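Leaving out a replicate was not possible with 1 array per group. No paired analysis was possible because each group held 1 sample and no test was run. Without detection calls, dim signals could not be told from background, which limits ratios near the floor. Fibroblast and matrix, immediate-early and interferon-stimulated genes stood apart in 12 of 12 alternatives fixed beforehand, smooth muscle in 11 and angiogenesis in 10 of 12, adipocyte markers in 10 of 11 and cholesterol synthesis in 10 of 12, cell cycle and ribosomal genes in 6 of 12 each. Of 1645 values of 172 named genes under alternatives, 61 had the opposite sign, 12 of them for genes at least 2-fold different, which are given below. The cause was not tested for any shift below, unless stated. The last alternative below, on genes with several probe sets, was chosen after seeing the data.

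With the floor at the 30th percentile, 203 genes were at least 2-fold higher and 505 lower, with it at the 70th percentile 37 and 25, and with no floor 967 and 1884. The floor sets both which genes enter (14920, 8018 and 18193 in these alternatives) and the value to which low signals are raised, and these were not separated. A pseudocount of 50 gave 189 lower genes. Fold thresholds of 1.5 and 3 gave 547 and 731, and 5 and 7, by construction. The median over probe sets gave 42 higher genes and the probe set closest to no change 39. With the floor at the 70th percentile 57.7% of probe-set pairs had the same sign.

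The following list medians crossed the threshold for standing apart or, in a list that stood apart, changed sign. Under quantile normalization the ribosomal list had -0.077 (6.88th percentile) and the survival list 0.21 (98.5th), and under loess -0.13 (2.525th) and 0.22 (98.2nd). With the floor at the 30th percentile, cell cycle had 0.12, cholesterol synthesis 0.18, fatty acid synthesis 0.21 and survival 0.23, and with no floor again 0.12, 0.18, 0.21 and 0.23. With it at the 70th percentile, castration-raised genes had -0.20 (2.13rd), angiogenesis -0.18 (5.52nd), cell cycle 0.29 (95.7th), fatty acid synthesis 0.23 (98.0th) and survival 0.23 (97.95th). With the median over probe sets, cell cycle had -0.002125 (82.2nd), the chaperone list -0.14 (2.145th), fatty acid synthesis 0.17 (98.8th), ribosomal genes -0.11 (6.28th) and survival 0.16 (98.1st). Without suffixed probe sets, ventral secretory genes had -0.28 (0.08th), smooth muscle -0.21 (2.705th), macrophages -0.40 (0.71st), cell cycle -0.048 (63.9th) and ribosomal genes -0.10 (23.7th). With the probe set closest to no change, angiogenesis had -0.14 (11.4th), macrophages -0.26 (1.24th), lymphocytes 0.25 (97.8th), adipocytes 0.12 (92.4th), cell cycle -0.004437 (77.5th), fatty acid synthesis 0.14 (99.1st) and ribosomal genes -0.027 (26.5th). With the mean over members, ERK pathway genes had 0.19 (99.3rd) and ribosomal genes -0.065 (2.5th). Medians of lists that did not stand apart had the opposite sign in 18 values, among them lymphocytes at -0.092 with no floor, and lymphocytes at -0.014, p53 targets at -0.059 and hypoxia-induced genes at -0.045 with the median over probe sets. With the probe set closest to no change they were p53 targets at -0.054, TGF-beta genes at -0.051 and basal markers at 0.061, and with the floor at the 70th percentile polyamine genes at -0.033.

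Genes at least 2-fold different had the opposite sign under other choices of probe set. With the median over probe sets Gpaa1 had a log2 ratio of -0.42 and Braf of -0.035, and without suffixed probe sets Ints14 had 0.15. With the probe set closest to no change, Gpaa1 had -0.42, Acvr1c -0.27, Braf -0.004007, Ints14 0.15, Dscam 0.28, Snhg11 0.26, Nup62 0.32, Slc22a12 0.19 and Pdia4 -0.082, of which those of Acvr1c, Dscam, Slc22a12 and Pdia4 are bounds. Kept to genes with at least 2 probe sets above the floor that all went the same way, a rule chosen after seeing the data, 10 genes were higher and 15 lower, by construction.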

Other observations

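Genes read by several probe sets gave a second view, by a rule set after seeing the data. Of 2180 genes with at least 3 probe sets above the floor, all probe sets were at least 1.5-fold higher on the array labelled knockout in 1 gene and at least 1.5-fold lower in 5. The higher gene was Tnpo3, a nuclear import receptor for splicing factors, with a median log2 ratio of 0.91. The lower genes were S1pr3, a receptor for sphingosine 1-phosphate, with a median of -0.97, Zhx3 with -0.81 or lower, Lztr1, an adaptor that lowers RAS levels, with -0.79, the MHC class II chain H2-Ab1 with -0.72 or lower, and Atp6v0a2, a subunit of the vacuolar proton pump, with -0.67. When log2 ratios were shuffled among the probe sets of these genes 100 times, the highest counts were 2 higher and 2 lower genes, with medians of 0 and 0. The count of lower genes was thus above all 100 shuffles and the count of higher genes was not. The shuffles ignored signal and treated probe sets of a gene as independent readings. A count above them therefore need not mean that the genes differed. Probe sets of the same gene share the RNA of the same 2 samples, so this says nothing about the spread between animals.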
